A study of Homo sapiens with 8 samples.

How the data were processed

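Chromatin from A2780, a human ovarian carcinoma cell line, was immunoprecipitated with an antibody against γH2AX, the phosphorylated histone H2A variant that accumulates around DNA breaks, and sequenced. The 8 samples form 4 groups of 2: untreated cells, cells given cisplatin, cells given Pt-ttpy, and input chromatin of untreated cells that was not immunoprecipitated. Per the labels' protocols, each drug was given at its own IC80 for 96 hours, chromatin was sonicated to fragments of 200 to 700 bp, and single reads of 50 bases were taken on an Illumina HiSeq instrument. The submitters' processing notes name BWA 0.7.5, MACS2 2.1.0 and the human build hg19. Calling settings and the handling of replicates are not given in the sources used here. The names of both treated lists carry a tag for untreated beside that of the drug. This may mean that they were called against the untreated samples, but the control used for each list is not stated.

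The data used here are 3 deposited peak lists, 1 for the untreated, 1 for the cisplatin and 1 for the Pt-ttpy group. The labels tie both replicates of a group to the same list, so each list was treated as 1 sample without replicates, and no p-value between conditions was computed. Input values were not analysed here. For each peak the authors deposited a fold enrichment ratio over background, a -log10 p-value and a -log10 q-value from the peak caller, a score that is 10 times the -log10 q cut to a whole number, and the summit position. These values are the authors' own and were used only to describe, rank or filter peaks within a list.

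The fold values were examined for the background behind them. Within each deposited list the fold took only 181 (untreated), 186 (cisplatin) or 183 (Pt-ttpy) distinct values, spaced at whole multiples of 0.301, 0.173 and 0.129, and each fold went with 1 p-value. With fold taken as (pileup + 1)/(background + 1), the spacing gives a background pileup of 2.33 for the untreated and 4.78 for the cisplatin list. For the Pt-ttpy list it gives 5.18 after a scaling of the pileup by 0.798, or 6.49 unscaled. Poisson tail probabilities computed from these pileups and 1 constant background per list differed from the deposited -log10 p-values by at most 0.00132. The fold of a peak is therefore relative to a genome-wide constant, not to the untreated or input signal at the same position. Read totals are not in the lists and the depth is otherwise unknown. The lists differed in background pileup, so their peaks were not called on equal terms. Intervals given here do not cover the variation between cultures.

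Peak numbers in the names ran without a break in both treated lists. In the untreated list they reached 18049, of which 8848 were missing. In that list 763 numbers appeared on more than 1 piece, and 2170 summits lay outside their own region. Why numbers are missing is not given in the sources used here.

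Peaks on chromosomes 1 to 22 and X entered the comparisons, each as 1 region. Chromosome lengths and the large gaps next to the centromeres (with the short arms of the acrocentric chromosomes) were entered from general knowledge of hg19. They were checked against the lists: 0 regions lay inside a gap or beyond a chromosome end. Overlap of 2 lists was the share of regions sharing at least 1 bp with the other list, set against 1000 random placements of the regions on their own chromosomes outside the gaps. The share within 1 Mb of a chromosome end was set against the same kind of placement. A value outside the central 95% of the placements was taken to differ from chance placement. Differences between lists in the share of regions at a location carry 95% intervals from 1000 bootstrap resamples of 5 Mb genome blocks. These intervals cover the variation along the genome only. Shares near centromere gaps and on the long arm of chromosome 1 beyond 5 Mb from the gap, and the comparison of chromosome arms, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

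The code was tested on simulated data. For Pt-ttpy on untreated overlap with 3000 random regions, 3 of 40 tests fell outside the 95% range with no effect planted, and with 20% of regions planted on the untreated list the mean recovered was 20%. For 17789 Pt-ttpy regions at chromosome ends with a planted weight of 3, the mean ratio was 2.92. In both checks the simulated regions were placed independently of each other, whereas the real regions are clustered. They test the code and do not give the rate at which clustered lists fall outside the range. For the Pt-ttpy list parted at random, with simulated location marks and no true difference, 192 of 200 bootstrap intervals held 0. Real locations are fixed by position and the lists were called separately. This check therefore does not give the coverage of the intervals between lists.

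The tests of overlap, of chromosome ends and of Pt-ttpy against cisplatin at chromosome ends, the rule for named regions and most alternatives were chosen before the data were examined. The rule named the 10 regions of highest -log10 q and the 5 densest 1 Mb windows per list. Breaking ties in -log10 q by width was decided after the ties were seen. The alternatives were a stricter q, merging of near regions, other overlap limits, equal numbers of top regions, circular shifts for overlap, other distances to chromosome ends and removal of regions shared with the untreated list. Circular shifts for chromosome ends, joining the pieces of untreated peaks, placement away from centromere gaps and leaving out the long arms of chromosomes 1 and 4 were added after the data were seen. The planned tests of G-quadruplex motifs, GC content, gene location and gene lists need the hg19 sequence or annotation, which was not used here, so no gene is named and sequence content was not analysed here.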

Results

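The series asked where DNA damage lies in the genome of A2780 cells after cisplatin, which crosslinks DNA, and after Pt-ttpy, a platinum complex that binds G-quadruplexes (4-stranded structures of guanine-rich DNA). Damage was read as γH2AX regions. The data were 1 peak list per condition, each tied by the labels to 2 samples, and the values below have no replicates. On chromosomes 1 to 22 and X the untreated list held 9709 regions, the cisplatin list 25671 and the Pt-ttpy list 17789. The constant background pileup behind the folds was 2.33 in the untreated, 4.78 in the cisplatin and 5.18 in the Pt-ttpy list, where pileups were scaled by 0.798, and 8848 of the 18049 peak numbers of the untreated list were missing from it.

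The γH2AX regions as called were short and covered little of the genome in all 3 lists. The median width was 164 bp in the untreated, 169 bp in the cisplatin and 185 bp in the Pt-ttpy list. The narrowest region was 101 bp in both treated lists and 1 bp in the untreated list, where 763 numbers appeared on more than 1 piece. These are widths of called peaks, with medians below the fragment size of 200 to 700 bp. They do not measure how far γH2AX spreads around a break. The regions covered 3038 kb in untreated cells, 7966 kb after cisplatin and 6473 kb after Pt-ttpy, or 0.106%, 0.279% and 0.227% of the assembled sequence outside the large gaps. The cisplatin list was 2.64 times and the Pt-ttpy list 1.83 times as long as the deposited untreated list. These ratios rose to 3.97 and 2.26 when regions within 1 kb were merged and fell to 1.68 and 1.43 with a -log10 q of at least 5. Against the 17540 untreated peak numbers placed on chromosomes 1 to 22 and X, with the missing ones counted between their retained neighbours, they were 1.46 and 1.01. The cisplatin list was 1.44 times as long as the Pt-ttpy list, 1.76 times after merging and 1.17 times with the stricter q. The median fold over the list's own background was 5.71 in the untreated, 3.64 in the cisplatin and 3.91 in the Pt-ttpy list. The folds have different backgrounds and do not give an order of signal between lists.

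The strongest regions lay next to the centromeres in all 3 conditions. By -log10 q, 18 untreated, 27 cisplatin and 36 Pt-ttpy regions were tied at the highest value of their list, and 16, 25 and 31 of these lay within 5 Mb of a centromere gap. All 27 tied cisplatin and all 36 tied Pt-ttpy regions overlapped an untreated region. The widest was on chromosome 16 (hg19), just beyond the centromere gap. It spanned 46385792 to 46410157 in the untreated list, 46385795 to 46414546 in the cisplatin list and 46385798 to 46414558 in the Pt-ttpy list. A block on chromosome 10 next to the centromere gap was called from 42376236 to 42385729, with further pieces up to 42397285, in untreated cells. It was called from 42376249 to 42385727 and from 42385876 to 42397295 after cisplatin, and as 1 region from 42374546 to 42397297 after Pt-ttpy. The region at 92315737 to 92326168 on chromosome 2 in the cisplatin list, matched by 92315732 to 92326162 in the Pt-ttpy list, ended at the edge of the centromere gap. Of the 10 named regions, 9 in the untreated and all 10 in each treated list lay within 5 Mb of a gap. The exception was at 106503 to 111643 on chromosome 18, near the end of the short arm. The highest pileup was 200 in the untreated and 202 in both treated lists, so the top regions are at a shared ceiling and cannot be ranked against each other.

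Of the 5 densest 1 Mb windows of each list, 2 were among the 5 of all 3 lists, 4 were common to the treated lists, and the untreated list had 2 in common with cisplatin and 3 with Pt-ttpy. The window from 9 to 10 Mb on chromosome 21, next to the short-arm gap, was the densest in each list, with 417 untreated, 496 cisplatin and 489 Pt-ttpy regions. The windows from 142 to 143 and from 143 to 144 Mb on chromosome 1 held 403 and 321 untreated, 374 and 446 cisplatin, and 378 and 425 Pt-ttpy regions. At the end of the long arm of chromosome 4, from 190 to 191 Mb, there were 243 untreated, 439 cisplatin and 424 Pt-ttpy regions. On chromosome 16 the window from 32 to 33 Mb held 193 untreated, 458 cisplatin and 384 Pt-ttpy regions, and that from 33 to 34 Mb held 224, 422 and 353. The untreated list also placed 302 regions at 49 to 50 Mb on chromosome 4 (359 cisplatin, 363 Pt-ttpy) and 296 at 22 to 23 Mb on chromosome 15 (409 cisplatin, 334 Pt-ttpy).

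Nearly every region kept in the deposited untreated list was also called after either drug. The missing untreated numbers do not enter this share. Of the untreated regions, 96.1% overlapped a cisplatin region and 95.1% a Pt-ttpy region, where random placement gave means of 0.970% and 0.740%. In the other direction 27.3% of cisplatin regions and 39.5% of Pt-ttpy regions overlapped an untreated region, against 0.337% and 0.361% by random placement. All of these lay outside the central 95% of 1000 placements. The remaining 18655 cisplatin and 10768 Pt-ttpy regions were called only in treated cells as deposited, with the reservation that the untreated list lacks 8848 of its peak numbers. They were weaker within their own lists, with a median fold of 3.29 for cisplatin and 3.39 for Pt-ttpy, against 6.06 and 5.72 for regions on the untreated list. The whole long arm of chromosome 1 held 43.4% of these cisplatin regions and 34.5% of these Pt-ttpy regions.

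**Figure D1:**
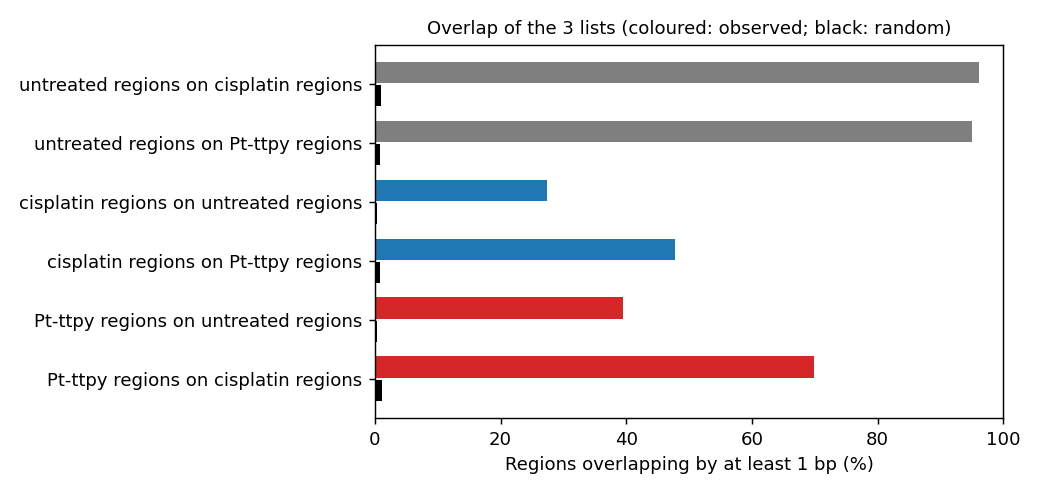
Share of regions of one list (colour) that overlap a region of another list by at least 1 bp, in percent, for the 6 ordered pairs of lists, with the mean of 1000 random placements in black. Regions kept in the untreated list overlap the cisplatin list at 96.1% and the Pt-ttpy list at 95.1%, while 27.3% of cisplatin and 39.5% of Pt-ttpy regions lie on untreated regions.

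The 2 treated lists had many places in common, many of them also on the untreated list. Of the Pt-ttpy regions 69.9% overlapped a cisplatin region, and of the cisplatin regions 47.8% overlapped a Pt-ttpy region, against 1.11% and 0.784% by random placement. Of these shared regions, 6887 Pt-ttpy and 6812 cisplatin regions also lay on an untreated region. Among the regions off the untreated list, 5547 Pt-ttpy regions lay on a cisplatin region and 5221 did not. In the other direction, 5449 cisplatin regions lay on a Pt-ttpy region and 13206 did not. Missing untreated numbers could stand for up to 6285 of the 10768 Pt-ttpy and 7732 of the 18655 cisplatin regions off the untreated list. With 9709 top regions taken from each list, the shared part was 80.5% of Pt-ttpy and 79.2% of cisplatin regions. Among regions more than 5 Mb from a centromere gap, 52.1% of Pt-ttpy regions lay on cisplatin regions and 27.6% the other way. The folds and p-values of both lists follow a background that is constant over the genome, so no control signal specific to a position entered them. For the same reason these values were not corrected for copy number or repeated sequence at a position. Random placement cannot tell shared damage from such a shared cause.

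To ask whether damage favoured telomeres, the distance to the chromosome ends was examined. Telomere repeats are largely missing from the assembly, so the values describe subtelomeric sequence. Regions lay within 1 Mb of a chromosome end in 6.05% of the untreated (587), 4.66% of the cisplatin (1195) and 5.998% of the Pt-ttpy list (1067). These shares were 3.85, 3.39 and 4.12 times those of random placement. Within 100 kb the ratios were 12.9, 9.78 and 11.7. The long arm of chromosome 4 alone held 45.7% of the untreated, 41.1% of the cisplatin and 44.5% of the Pt-ttpy regions within 1 Mb of an end. Without that arm, left out after its share was seen, the ratios were 2.12, 2.05 and 2.34. Pt-ttpy minus untreated was -0.0478 percentage points (95% interval -1.61 to 1.08) and cisplatin minus untreated -1.39 points (-4.28 to 0.315), so both intervals held 0. With 5 Mb in place of 1 Mb the untreated ratio was below 1 (0.903), the cisplatin ratio (1.03) lay within the random range and the Pt-ttpy ratio fell to 1.07. With circular shifts, which keep the regions' clusters together, the untreated ratio no longer lay outside the random range.

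Regions at the very tips of chromosomes were called without treatment. Their folds were not corrected for repeated sequence, and input values were not used here. Whether reads of repeats from other places pile up at the tips was not tested, so these regions are not read as damage at telomeres. Within 12 kb of a chromosome end, a limit chosen after the data were seen, the untreated list held regions on 7 arms, the cisplatin list on 11 and the Pt-ttpy list on 9, and the same 7 arms appeared in all 3 lists. At the tip of the short arm of chromosome 5 the region ran from 10015 to 11775 in untreated cells, with a fold of 33.1 where the median of its list was 5.71. It ran from 10014 to 11782 after cisplatin, with a fold of 22.8 in a list of median 3.64, and from 10013 to 11780 after Pt-ttpy, with a fold of 19.5 in a list of median 3.91. At the tip of the long arm of chromosome X the region from 155260029 to 155260396 in the untreated list had a fold of 31.6. The matching regions had folds of 22.3 in the cisplatin and 18.6 in the Pt-ttpy list, which place each high within its own list and give no order between lists. The tip of the long arm of chromosome 19 held a region in both treated lists, at 59117016 to 59117228 for cisplatin with a fold of 3.64 and at 59117027 to 59117129 for Pt-ttpy with a fold of 3.26. The tip of the long arm of chromosome 5 also had regions in both treated lists, the strongest with a fold of 5.71 after cisplatin and of 3.78 after Pt-ttpy.

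Pericentromeric sequence held the largest part of each list. Regions within 5 Mb of a centromere gap made up 73.3% of the untreated, 44.3% of the cisplatin and 57.0% of the Pt-ttpy list, where this sequence is 7.25% of the assembled genome. The untreated share is that of the list as deposited. With its missing numbers placed between their retained neighbours it was between 51.2% and 53.7%, below the Pt-ttpy share. The long arm of chromosome 1 beyond 5 Mb from the gap, 3.56% of the genome, held 388 untreated regions (4.00%), 7528 cisplatin regions (29.3%) and 3298 Pt-ttpy regions (18.5%). The regions there were close to the calling limit, with a median fold of 3.12 in the cisplatin and 3.13 in the Pt-ttpy list, and 13.2% and 14.6% of them had a -log10 q of at least 5. They were spread over the arm: 102 of its 102 windows of 1 Mb held 5 or more cisplatin regions and 101 held 5 or more Pt-ttpy regions, against 8 for untreated regions. Of the missing untreated peak numbers, 2587 fall on this part of the arm by their neighbours' positions, more than the 388 regions kept there.

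**Figure D2:**
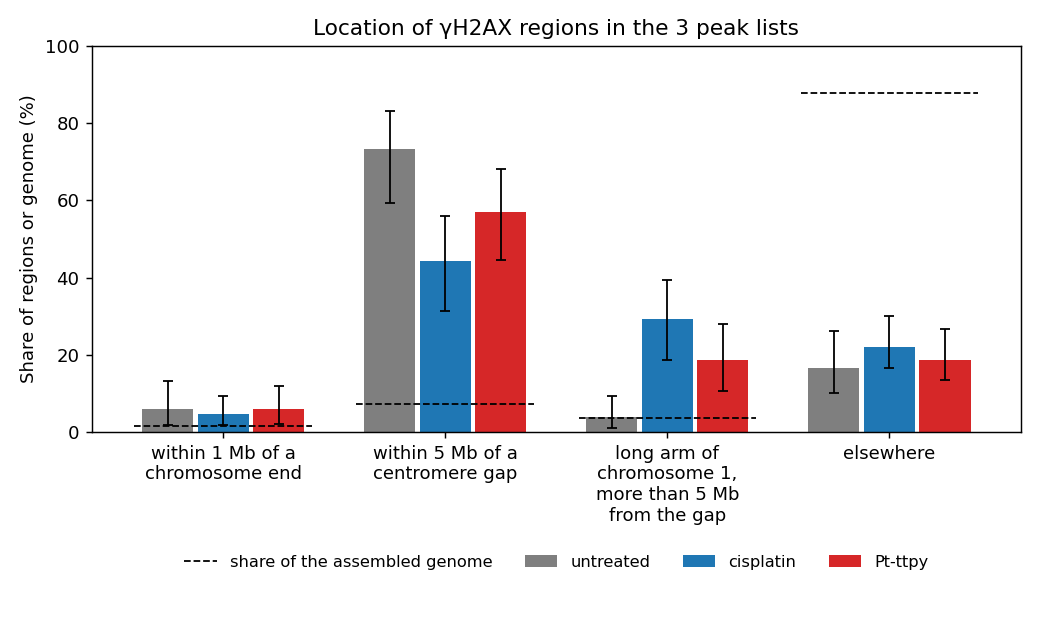
Share of regions of each list, in percent, at 4 locations, with 95% block bootstrap intervals over 5 Mb genome blocks as error bars and the share of the assembled genome as dashed lines; the locations are not fully exclusive. Regions within 5 Mb of a centromere gap make up 73.3%, 44.3% and 57.0% of the untreated, cisplatin and Pt-ttpy lists, and the long arm of chromosome 1 beyond 5 Mb from the gap holds 29.3% of the cisplatin list. Untreated shares are those of the deposited list, which lacks 8848 of its peak numbers.

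**Figure D3:**
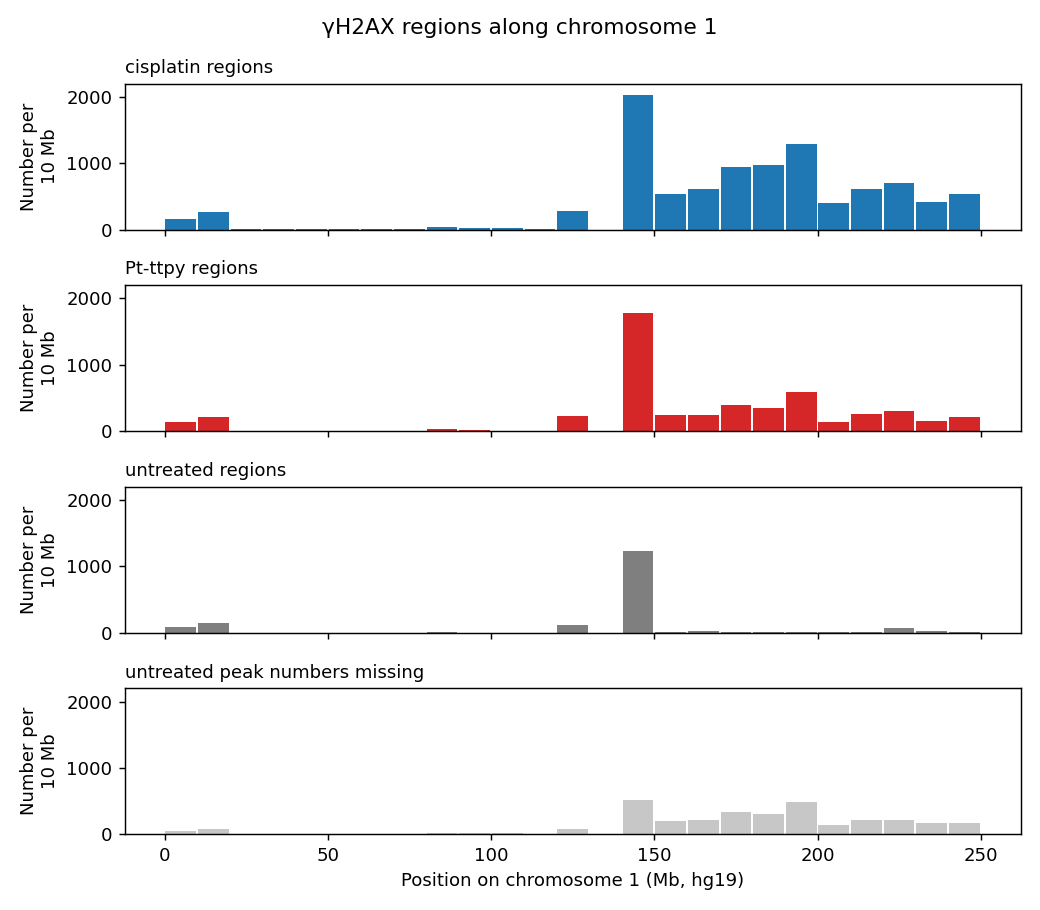
Number of regions per 10 Mb along chromosome 1 (hg19, Mb) in the cisplatin, Pt-ttpy and untreated lists, and of peak numbers missing from the untreated list, spread evenly between the retained neighbours. Between 190 and 200 Mb there are 1292 cisplatin, 592 Pt-ttpy and 13 untreated regions and 489 missing untreated numbers.

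Both drugs are platinum complexes and were given at their own IC80 for the same 96 hours. Their lists differed in where the regions lay. The Pt-ttpy list had a larger share near centromere gaps than the cisplatin list, by 12.6 percentage points (95% interval 10.1 to 14.9). It had a smaller share on the long arm of chromosome 1 beyond 5 Mb from the gap, with a difference of -10.8 points (-13.7 to -7.10). Its share within 1 Mb of chromosome ends was higher by 1.34 points (0.256 to 3.34), and by 0.620 points (0.176 to 1.29) without the long arm of chromosome 4. Without the whole long arm of chromosome 1 the difference near gaps was 7.47 points (5.50 to 9.64). Both arms were left out after their shares were seen. In numbers, there were 1.12 cisplatin regions per Pt-ttpy region near centromere gaps, and, away from gaps and ends, 2.29 on the long arm of chromosome 1 and 1.69 on the other arms. Away from gaps and ends, cisplatin regions were denser than Pt-ttpy regions on 40 of 40 chromosome arms. With 9709 top regions from each list, the difference near gaps was 1.62 points (0.764 to 2.56), that on the long arm of chromosome 1 beyond 5 Mb from the gap was -0.803 (-1.55 to -0.376), and that at chromosome ends was -0.0721 (-0.341 to 0.233). The intervals cover variation along the genome and not that between cultures, so they compare these lists, not the drugs in general. The lists also differed in unscaled background pileup (4.78 for cisplatin, 6.49 for Pt-ttpy) and in lowest peak pileup (14 and 19). With 1 list per drug, an effect of the drug cannot be told apart from one of calling depth.

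Outside the long arm of chromosome 1, regions away from gaps and ends were sparse. The median over the other arms was 0.372 untreated, 1.67 cisplatin and 0.861 Pt-ttpy regions per Mb. Untreated values by arm are those of the deposited list, which lacks 8848 of its peak numbers, and missing numbers were not added to them. The long arm of chromosome 16 was the densest of these in both treated lists, with 8.23 cisplatin and 6.21 Pt-ttpy regions per Mb (313 and 236 regions) against 57 untreated regions. Of the arms named here after their values were seen, the long arm of chromosome 3 held 118 cisplatin, 25 Pt-ttpy and 9 untreated regions, and the short arm of chromosome 7 held 50, 8 and 7. The long arm of chromosome 8 held 200 cisplatin, 135 Pt-ttpy and 177 untreated regions, the 1 arm of 40 with fewer Pt-ttpy than untreated regions.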

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

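All tests weighed here except that of high pileups were chosen after the results they bear on had been seen, and 3 of them replaced earlier versions. The untreated share near gaps replaced a difference between lists. The intervals with missing numbers replaced a shift of the lists, and were later widened from 1 to 3 classes of length, which took the lowest ratio below its limit. The test of depth was revised more than once: the order of the treated lists, which does not bear on treated against untreated, was tried, replaced by the full untreated numbering, taken back and then dropped for the background pileup.

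The shares of regions near centromere gaps, on the long arm of chromosome 1 beyond 5 Mb from the gap and near chromosome ends differed between the deposited lists of the drugs, with block bootstrap intervals that exclude 0 and Pt-ttpy minus cisplatin at 12.6, -10.8 and 1.34 percentage points. With equal numbers of top regions the first pair shrank to 1.62 and -0.803 points, and the difference at ends was lost, at -0.0721 (-0.341 to 0.233), as it was with a -log10 q of at least 5, at 0.0630 (-0.341 to 0.739). Regions were also placed on chromosome Y, which no comparison used, with 449 in the cisplatin and 433 in the Pt-ttpy list against 380 in the untreated list. Whether reads were misplaced there was not tested, so these counts are not read as damage on chromosome Y. The untreated list lacks 8848 of its peak numbers.

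Treated regions on the long arm of chromosome 1, taken here beyond 5 Mb from the gap, far outnumbered the deposited untreated ones. Treatment as the whole cause is argued against by the untreated numbering, since missing untreated numbers are 13.4 times as dense on the long as on the short arm. With missing numbers counted, the untreated arm holds 29.0 numbers per Mb, against 32.4 Pt-ttpy and 74.0 cisplatin regions per Mb. Extra copies of the arm, called against a constant background, were left undecided: at least 99.0% of its 1 Mb windows held 5 or more regions in each treated list, but all 10 windows of 10 Mb, seen before, already averaged at least that many per Mb, so the test could hardly have failed. Copy number was not measured here, any other cause that acts on the whole arm would look alike, and a contribution of cisplatin stays open.

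The longer treated lists may come in part from the removal of untreated peaks before deposit. Set against the 17540 retained and missing untreated numbers on chromosomes 1 to 22 and X, the cisplatin list was 1.46 times as long. The Pt-ttpy list was 1.01 times as long. In number the Pt-ttpy list is then hardly longer, though its regions need not lie where the missing numbers fell. Intervals between retained untreated peaks held a treated region off the untreated list more often where numbers were missing. This was so in both lists and 3 classes of length, but the lowest ratio was 1.46 (1 to 10 kb, cisplatin, 88.4% against 60.4%), below the 1.5 asked for. With 60.4% already holding a region, that ratio had little room to rise. In that class, intervals with missing numbers were also longer (median 2.45 against 1.72 kb). The other cisplatin ratios were 1.64 at 10 to 100 kb and 2.05 at 100 kb to 1 Mb. For Pt-ttpy the ratios were 1.58, 1.89 and 3.74, from the shortest to the longest class. In the earlier version, treated regions could account for 93.7% (cisplatin) and 78.3% (Pt-ttpy) of missing numbers against means of 39.3% and 29.7% after shifts, which also break up clusters. If each number stands for 1 region, missing numbers account for at most 7732 of the 18655 cisplatin and 6285 of the 10768 Pt-ttpy regions off the untreated list. This limit leaves out parts that may have been cut from retained peaks. Joining the pieces of untreated peaks left 27.3% of cisplatin and 39.5% of Pt-ttpy regions on the untreated list, as without joining. Parts cut from the ends of peaks cannot be seen. Depth and treatment cannot be told apart, because each condition has 1 list and both treated lists have at least 2.05 times the untreated background pileup.

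Regions gather next to the centromere gaps in every list. Treatment as the origin is argued against by the untreated list, of which 73.3% lies there (95% interval 59.4% to 83.1%) against 7.25% of the genome; in the earlier version, Pt-ttpy minus untreated was -16.3 points, a difference that the missing numbers distort. Repeated sequence piling up on few assembled copies is a possible explanation that was not decided. Of regions with a pileup of at least 100, at least 82.5% per list lay near a gap or end, past the 80% set beforehand, but the excess over other regions, with an interval added later, was 3.27 points in the untreated list (-11.3 to 15.7, which holds 0), 35.7 for cisplatin and 23.3 for Pt-ttpy. Damage in pericentromeric repeats of untreated cells was not tested, since input values were not used here.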

How the results depend on the processing

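All 46 alternatives for the overlap of lists kept the excess over random placement outside the 95% range, with ratios from 11.5 to 311. The number of regions depended on the setting: merging regions within 1 kb left 3379 untreated, 13416 cisplatin and 7639 Pt-ttpy regions, a -log10 q of at least 5 left 12034 cisplatin and 10248 Pt-ttpy regions, and leaving out the whole long arm of chromosome 1 (chosen after seeing the data) left 16627 cisplatin regions. After merging, the Pt-ttpy list keeps its place between the other lists. For chromosome ends, 18 of 21 alternatives gave the same call. With 5 Mb in place of 1 Mb the untreated ratio reversed to 0.903 and the cisplatin ratio fell within the random range at 1.03; with circular shifts (chosen after seeing the data) the untreated ratio was 3.93 but lay within it. That call varied between runs of 200 shifts, so 1000 were drawn. The cause was not tested. The higher Pt-ttpy than cisplatin share at chromosome ends was not kept among stronger regions: it was 0.0630 points with a -log10 q of at least 5 and -0.0721 with equal numbers of top regions. The other 10 alternatives for differences between the drugs gave the same call, 7 of them for shares near gaps or on chromosome 1 that were chosen after seeing the data, with the difference near gaps between 1.62 and 12.7 points. Depth limits what weak regions can show, since the untreated list was called at a background pileup of 2.33, the cisplatin list at 4.78 and the Pt-ttpy list at 5.18. No paired analysis was possible because each condition has 1 list and no values per replicate, and for the same reason no replicate was left out. Alternatives for motifs, GC content, gene location and gene lists were not run, as hg19 sequence and annotation were not used here.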

Other observations

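Putting the missing numbers back changes the picture of untreated cells, a description chosen after the data were seen. With each missing number placed between its retained neighbours, 17540 numbers lie on chromosomes 1 to 22 and X. Between 51.2% and 53.7% of these lie within 5 Mb of a centromere gap, where the deposited untreated list has 73.3%, the Pt-ttpy list 57.0% and the cisplatin list 44.3%. The long arm of chromosome 1 beyond 5 Mb from the gap takes 16.8% of the numbers, against 4.00% of the deposited untreated, 18.5% of the Pt-ttpy and 29.3% of the cisplatin regions.

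Treated regions off the untreated list differed in location between the drugs as deposited. Near centromere gaps lay 46.2% of the Pt-ttpy and 33.5% of the cisplatin regions of this kind, a difference of 12.7 points (95% block bootstrap interval 9.71 to 14.8). Over whole lists the difference near gaps fell from 12.6 points to 4.62 with a -log10 q of at least 5 and to 1.62 with equal numbers of top regions, and missing untreated numbers could stand for up to 41.4% of the cisplatin and 58.4% of the Pt-ttpy regions off the untreated list. Of the 13206 cisplatin regions on neither other list, 52.7% lay on the whole long arm of chromosome 1 and 22.4% near a gap, with a median fold of 3.29. Of the 5221 Pt-ttpy regions on neither other list, 48.8% lay on that arm and 30.8% near a gap, with a median fold of 3.26. No region off the untreated list exceeded a fold of 9.17 after cisplatin or 9.98 after Pt-ttpy, while the lists reach 35.1 and 26.3.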
